A study of Homo sapiens with 51 samples.

How the data were processed

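RNA-seq was done on 51 libraries of B cells sorted by flow cytometry from human lymph nodes of 5 uninfected and 4 HIV-infected donors, in the 12 groups the labels give. Per the labels' protocols, cells were sorted into Trizol LS, RNA was cleaned with a Zymo kit and libraries were made with the NuGen Ovation SoLo kit. Per the submitters' processing notes, the authors made reads with bcl2fastq 2.17.1.14, aligned them with STAR 2.5.2 to hg19 and tested genes with DESeq2 (no version given). The deposited table holds raw counts, whole numbers per gene symbol and library, per the file headers and as checked on the values; the authors gave no lengths, coordinates or identifiers beside the symbols, so none are printed.

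The table has 22427 gene rows. 101 rows of sex-linked genes were removed before any test, since human donors are not described by them. Of the rows, 2160 had no count in any library. The table names no immunoglobulin constant or variable gene, so no antibody class or repertoire measure could be made. A RefSeq gene table of another assembly than hg19 (GRCh38) was used only for gene names and to find Y-linked genes.

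R 4.3.3 with edgeR 4.0.16 was used for the tests. Library sizes were scaled by the trimmed mean of M values (TMM), and genes were kept by filterByExpr at its default settings. Each comparison was fitted with the libraries of its own groups alone, with glmQLFit and glmQLFTest at their default prior count and no donor term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The standard error of a log2 fold change was taken as the change divided by the square root of the F statistic. CPM values use TMM-scaled library sizes over all 51 libraries.

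The 17 comparisons were HIV infection against none in naive, unswitched memory, memory and GC cells, memory, unswitched memory and GC cells against naive cells in uninfected and in infected donors, HIV-specific against IgG+ cells as memory and as GC cells, memory against GC cells within each of these 2 classes, and the difference of the infection effect between memory, unswitched memory or GC cells and naive cells. Infection compares different donors, while subsets were sorted from the same donors. Libraries of 1 donor correlated with each other across subsets, as deviations from group means, at 0.0512 to 0.51, against means of -0.094 to -0.0303 between donors, so the numbering of the donors was taken as a pairing. A donor term (replicate block) was tried as an alternative, fixed before the data were examined, for the subset, antigen class and difference comparisons.

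Gene lists, 32 in all with 664 genes, were fixed before the data were examined, and 647 genes were found, 11 of them under an older symbol. They were tested by camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, with an estimated correlation, and by fry, with Benjamini-Hochberg adjustment over the lists with at least 5 tested genes. Members were counted over all genes and adjusted over the list alone.

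Genes to name were chosen by a rule fixed before the data were examined: in each direction the 10 called genes with the largest log2 fold change, a mean of at least 20 CPM in the higher group and no overlap between the libraries of the groups, and any member of the lists. TBX21, ITGAX, CXCR3, FCRL5, CR2, CXCR5 and BCL6 were to be given in each comparison whether or not they passed. Of 119 such values 38 passed and all of these are printed, 79 did not pass and 2 were too low to test. Of those that did not pass, 62 are given only in the results table, with adjusted p of 0.097 or more. SORT1, OR2T10, KIAA1407, VASH2, RNGTT and C18orf1 were named after their values were seen.

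The alternatives were size factors by relative log expression in place of TMM, DESeq2 1.42.0 in place of edgeR, no low-count filter, one model over all 12 groups, the replicate block, and leaving out each library or, for the differences, each donor. The number of detected genes as a covariate was added after seeing the data. Groups of libraries were also regrouped in up to 100 splits, the real grouping among them, drawn at random where more were possible. Each of the 85 pairs of libraries within a group differed by more than sampling, with a chi-square per degree of freedom of at least 13.48, and 0 pairs were identical.

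The procedure was tested on simulated data made from the means and library sizes of the real libraries, with 200 genes changed 2- or 4-fold. The changed genes were drawn from those with a mean of at least 20 CPM, so the shares found do not cover lower genes. Each library was drawn independently, with no donor effect, so the shares may differ where a donor's libraries are paired. For infection in memory cells it found 52% of 2-fold and 100% of 4-fold changes among 11430 genes. For HIV-specific against IgG+ memory cells it found 51% and 98% among 11240 genes, for HIV-specific against IgG+ GC cells 34% and 95% among 11236, for GC against naive cells of uninfected donors 43% and 99% among 11110, and for the GC minus naive difference 11% and 65% among 12052. In the order of these 5 comparisons, 7.88, 5.1, 7.19, 4.7 and 5% of the calls were false.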

Results

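RNA was sequenced from 51 libraries of B cells sorted from human lymph nodes, in 12 groups, from 5 uninfected and 4 HIV-infected donors. Naive, unswitched memory, memory and germinal centre (GC) B cells were each sorted from every donor, giving 5 libraries per uninfected and 4 per infected group. From the infected donors, IgG-switched (IgG+) cells and IgG-switched cells labelled HIV-specific were sorted as well, each as memory and as GC cells. These gave 4 libraries per group, except IgG+ GC with 3. The total count per library ran from 4.69 to 12 M counts (M, mega), with a median of 5.92 M. By group it ran from 4.69 to 5.94 M in uninfected naive, 5.13 to 5.93 in uninfected unswitched memory, 5.11 to 6.20 in uninfected memory and 5.51 to 6.60 in uninfected GC cells. In infected donors the totals were 4.82 to 5.83 M for naive, 5.08 to 6.17 for unswitched memory, 5.35 to 6.95 for memory and 6.37 to 7.95 for GC cells. They were 5.12 to 6.79 M for IgG+ memory, 6.40 to 7.74 for IgG+ GC, 5.60 to 12 for HIV-specific memory and 5.12 to 7.0 for HIV-specific GC cells. Between 11882 and 15349 genes had at least 1 count in a library. Levels below are CPM, counts scaled to 1 M per library, as mean ± SD over the libraries of a group, with the n given here, and log2 fold changes are given ± SE. An adjusted p is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and for a gene list from camera. Totals cover counting error only.

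GC cells stood apart from all other subsets. The first principal component held 52.3% of the variance of the 2000 most variable genes. The 16 GC libraries lay between 58.0 and 108 on it, and the 31 naive, unswitched, memory and IgG+ memory libraries between -65.8 and -16.7. The 4 HIV-specific memory libraries lay between these sets, from -0.90 to 25.8. The second component held 9.22%.

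**Figure D1:**
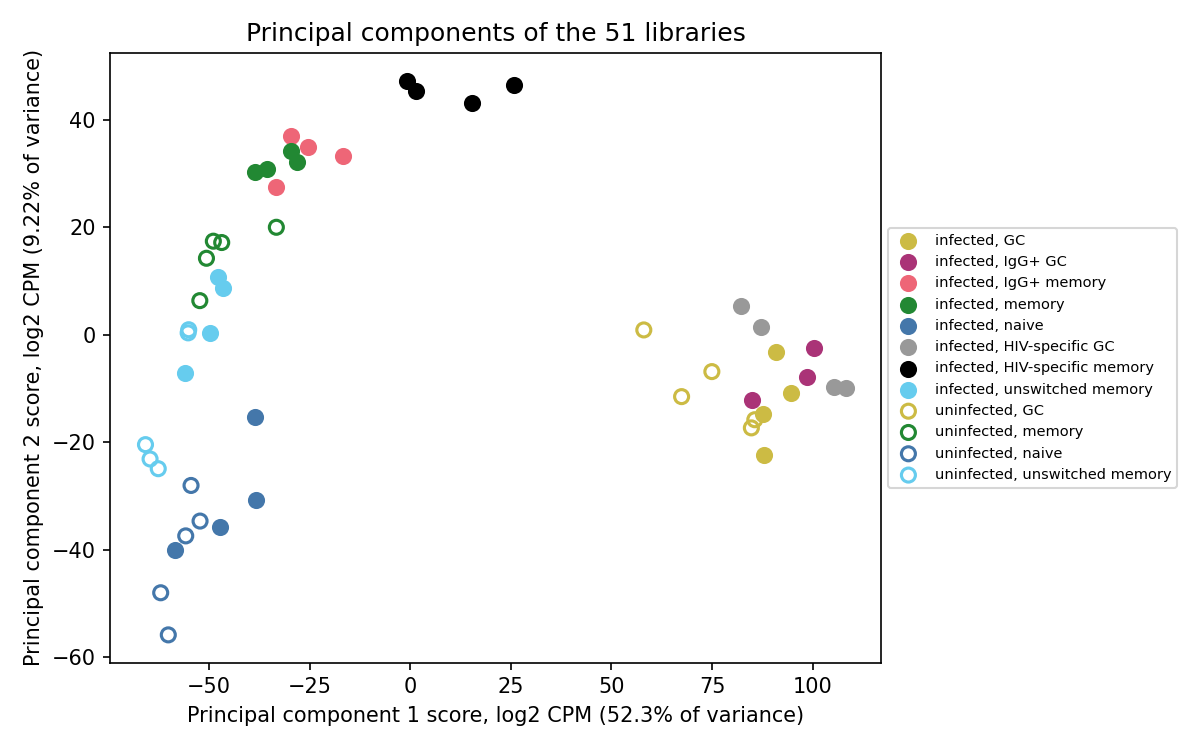
First and second principal components (axis units: scores on log2 CPM, with the share of variance) of the 51 libraries, 1 point per library, coloured by subset, with filled points for infected and open points for uninfected donors. The 16 GC libraries lie at 58.0 or above on the first component and the 4 HIV-specific memory libraries between -0.90 and 25.8.

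The first question was which genes distinguish memory from naive B cells in the uninfected lymph node. Memory cells carried transcripts known from antigen-experienced B cells. CD27, a costimulatory receptor used to sort memory cells, was at 42.6 ± 9.31 CPM in memory and 4.35 ± 6.49 in naive cells. CD80, a ligand for T cell costimulation, was at 73.8 ± 32.4 and 5.43 ± 4.79 CPM. TCL1A, a marker of naive cells, fell by 5.93 on the log2 scale, from 508 ± 34.7 to 8.01 ± 7.71 CPM. FCER2, the IgE receptor CD23, was at 313 ± 74.1 CPM in naive and 63.4 ± 27.4 in memory cells, and IL4R at 290 ± 58.7 and 47.0 ± 41.6. Of 30 tested genes of the memory list, 20 rose and 0 fell (camera adjusted p = 1.53e-32). Of 18 tested genes of the naive list, 10 fell and 0 rose (camera adjusted p = 3.48e-24). Adjusted over the list alone, these counts were 22 and 11. Among the largest changes, TOX, a nuclear factor, was at 73.1 ± 23.0 against 1.23 ± 1.73 CPM, and SPRY1, an inhibitor of growth factor signalling, at 0.942 ± 0.623 against 41.3 ± 12.5. ITGAX, which encodes CD11c, rose by 3.85 ± 0.81 (adjusted p = 0.00955; 2.51 without uninfected memory replicate 4, adjusted p = 0.0531), CXCR3 by 4.36 ± 0.74 (adjusted p = 0.00169), and FCRL5 fell by 1.01 ± 0.26 (adjusted p = 0.0353). In all, 303 genes were higher and 254 lower of 11181 tested. The count was 925 in one model over all groups. In 1 of the 5 uninfected memory libraries, replicate 4, summed T cell markers reached 1510 CPM against 51.7 in the next library, and the count without it was 516.

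Unswitched memory cells, which had not changed their antibody class, shared part of this change. CD27 rose by 3.48 ± 0.66 to 48.6 ± 9.87 CPM (adjusted p = 0.00784), and TCL1A fell by 3.62 to 41.4 ± 42.2 CPM. CD1C, a lipid-presenting molecule of marginal zone-like B cells, rose from 102 ± 28.9 to 267 ± 29.8 CPM (adjusted p = 0.002). COL4A3, a collagen chain, rose from 30.5 ± 17.9 to 363 ± 55.2 CPM, and FCRL4, an inhibitory Fc receptor-like protein, was at 15.1 ± 8.13 against 0.543 ± 0.482. Of 13 tested genes of the unswitched and marginal zone list, 5 rose and 1 fell (camera adjusted p = 2.27e-08). Adjusted over the list alone, 9 rose and 1 fell. In the memory list 7 of 28 genes rose, or 15 adjusted over the list alone (camera adjusted p = 4.07e-19). In the naive list 8 of 17 fell, with 8 adjusted over the list alone (camera adjusted p = 2.05e-18). These 3 calls and the 2 list calls of memory cells held with an estimated correlation. Of 10914 genes, 125 were higher and 83 lower. With a replicate block for the donor the total was 415 in place of 208, with DESeq2 359, in one model over all groups 615, and without uninfected naive replicate 1 it was 134.

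GC cells of uninfected donors were compared with naive cells for the genes of the GC reaction. BCL6, the transcription factor that the GC state requires, rose from 59.4 ± 21.2 to 649 ± 164 CPM. RGS13, a regulator of chemokine signalling, was at 864 ± 218 against 0.0727 ± 0.0996 CPM, and MKI67, a marker of dividing cells, at 779 ± 205 against 2.59 ± 2.07. All 39 tested proliferation genes rose (camera adjusted p = 2.55e-66), as did 30 of 31 genes of the GC list (camera adjusted p = 2.55e-66) and 14 of 18 dark zone genes, of which 1 fell (camera adjusted p = 6.42e-19). Adjusted over the list alone, the counts were 39, 30 and 15. S1PR1 fell by 4.09, CCR7 fell by 2.98 and BCL2 fell by 2.31 on the log2 scale. Of 40 interferon-stimulated genes, 23 fell and 4 rose, with the same counts adjusted over the list alone (camera adjusted p = 6.88e-07). These 4 list calls held with an estimated correlation. Of 30 ribosomal protein genes, 16 fell, or 21 adjusted over the list alone (camera adjusted p = 1.02e-05, adjusted p = 0.385 with an estimated correlation). CR2, the complement receptor CD21, fell by 0.83 ± 0.21 (adjusted p = 0.00899) and CXCR5, the follicle homing receptor, by 1.01 ± 0.15 (adjusted p = 0.000129). Of 11316 genes, 1804 were higher and 1477 lower, 3281 in all.

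The same subset contrasts were made in infected donors. In memory against naive cells, CD27 was at 47.1 ± 9.08 against 3.16 ± 4.43 CPM, CD80 at 63.9 ± 17.5 against 7.44 ± 4.32, and TCL1A at 6.46 ± 5.10 against 525 ± 60.8. CR2 fell by 0.95 ± 0.17 (adjusted p = 0.00595), CXCR5 by 0.62 ± 0.15 (adjusted p = 0.0252) and BCL6 by 1.06 ± 0.20 (adjusted p = 0.00882), while CXCR3 rose by 1.88 ± 0.32 (adjusted p = 0.00451). TBX21, which encodes T-bet, did not pass, at 36.2 ± 15.5 against 20.4 ± 13.3 CPM (adjusted p = 0.438). It was higher in memory than in naive cells of all 4 infected donors and passed with a replicate block, at 1.11 (adjusted p = 0.044). Of 31 memory list genes 19 rose, or 22 with 1 lower adjusted over the list alone (camera adjusted p = 6.26e-28), and of 17 naive list genes 11 fell, or 12 adjusted over the list alone (camera adjusted p = 4.74e-21). Both calls held with an estimated correlation. The total was 350 higher and 425 lower of 11262 genes, 775 in all. It was 1471 with a replicate block, 1211 with DESeq2, and 57 with the number of detected genes as a covariate, an alternative chosen after seeing the data. Without 1 of the HIV memory libraries, replicates 1 to 4, it was 471, 510, 501 and 497.

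In unswitched memory against naive cells of infected donors, CD27 rose by 3.68 ± 0.67 to 40.9 ± 2.71 CPM (adjusted p = 0.00788), COL4A3 was at 245 ± 77.8 against 18.9 ± 10.9, and TCL1A fell by 4.19 to 28.6 ± 9.67 CPM. IL21R, the receptor of a T follicular helper cytokine, was at 22.2 ± 10.6 against 167 ± 22.4 CPM. CXCR3 rose by 1.60 ± 0.38 (adjusted p = 0.0419) and BCL6 fell by 1.29 ± 0.23 (adjusted p = 0.00676). Of 30 memory list genes 11 rose, or 18 adjusted over the list alone (camera adjusted p = 7.21e-23), and of 17 naive list genes 10 fell, or 13 adjusted over the list alone (camera adjusted p = 1.15e-32). Both held with an estimated correlation. Of the 14 unswitched and marginal zone genes, 3 rose and 1 fell, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.107 with an estimated correlation). Of 11020 genes, 136 were higher and 140 lower, 276 in all. The total was 733 with a replicate block, 520 with DESeq2, 182 without HIV unswitched memory replicate 2 and 183 without replicate 4.

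In GC against naive cells of infected donors, BCL6 was at 684 ± 96.9 against 69.5 ± 13.8 CPM and MKI67 at 1080 ± 344 against 21.3 ± 26.4. S1PR1, the receptor that guides exit from lymphoid tissue, was at 1.37 ± 0.756 against 250 ± 17.5 CPM, and CCR7 at 1.15 ± 1.36 against 77.6 ± 19.5. ITGAX fell by 3.36 ± 0.82 (adjusted p = 0.00688) and FCRL5 fell by 1.5 ± 0.33 (adjusted p = 0.00355), CR2 fell by 1.15 ± 0.19 (adjusted p = 0.000511) and CXCR5 fell by 0.69 ± 0.15 (adjusted p = 0.00415). All 39 proliferation genes rose, also adjusted over the list alone (camera adjusted p = 7.2e-36, adjusted p = 0.0513 with an estimated correlation). In the GC list 30 of 31 genes rose, also adjusted over the list alone (camera adjusted p = 7.97e-43), a call that held with an estimated correlation. Of 41 interferon-stimulated genes, 34 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 1.66e-11, adjusted p = 0.28 with an estimated correlation). Of 11272 genes, 1950 were higher and 1999 lower, 3949 in all. The total was 2006 with the number of detected genes as a covariate.

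The central question was what differs with HIV infection in each subset. No donor was in both sets, so any other difference between infected and uninfected donors cannot be told apart from infection. The term infection effect is used here for the difference between these sets. In naive B cells, interferon genes and genes of T-bet-expressing B cells were higher in infected donors. The guanylate-binding proteins GBP1, GBP2 and GBP4, interferon-gamma targets, were at 195 ± 86.7 against 32.6 ± 8.75, 74.7 ± 43.9 against 11.6 ± 3.55 and 519 ± 260 against 108 ± 15.2 CPM. TBX21 rose by 4.04 ± 0.67, from 1.20 ± 0.36 to 20.4 ± 13.3 CPM (adjusted p = 0.0154), ITGAX by 3.78 ± 0.71, from 1.47 ± 0.906 to 20.6 ± 15.6 (adjusted p = 0.0415), and FCRL4 by 4.78 ± 0.86, from 0.543 ± 0.482 to 16.1 ± 13.2 (adjusted p = 0.0279). Among infected naive libraries, replicate 4 was lowest for TBX21, ITGAX and FCRL4, at 2.23, 5.07 and 2.03 CPM. The highest uninfected naive values were 1.79, 2.68 and 1.33 CPM. SIGLEC6, a sialic acid-binding receptor, FAS, the death receptor CD95, and DNAH8, a dynein chain, were at 21.3 ± 7.85 against 1.16 ± 0.831, 22.7 ± 7.54 against 2.38 ± 1.22 and 36.1 ± 20.8 against 0.387 ± 0.34 CPM. CXCR3 was at 13.7 ± 5.60 against 1.04 ± 1.44 CPM, which did not pass (adjusted p = 0.134), nor did FCRL5 at 731 ± 211 against 315 ± 145 (adjusted p = 0.154). Of 42 interferon-stimulated genes 6 rose, and 34 adjusted over the list alone (camera adjusted p = 1.29e-59). Of 24 interferon-gamma genes 6 rose, and 14 adjusted over the list alone (camera adjusted p = 1.51e-39). Of 25 genes high in T-bet-expressing memory cells 5 rose, and 9 adjusted over the list alone (camera adjusted p = 7.77e-15). These 3 calls held with an estimated correlation, and 0 members fell. Of 27 GC list genes 24 had a positive change, 0 past the test over all genes and 1 adjusted over the list alone (camera adjusted p = 2.2e-06, adjusted p = 0.0208 with an estimated correlation). Of 23 proliferation genes 20 had a positive change and of 24 immediate-early and stress genes 3, with 0 past either adjustment (camera adjusted p = 0.00427 and 0.00288, adjusted p = 0.437 and 0.439 with an estimated correlation). Over 10997 genes, 23 were higher and 0 lower, while 832 had an unadjusted p under 0.05. DESeq2 called 115 (20 of them lower), edgeR 99 in one model over all groups, 96 without a low-count filter and 72 with the number of detected genes as a covariate. Without HIV naive replicate 3 the count was 7, without HIV naive replicate 1 it was 74, and without uninfected naive replicate 4 it was 12.

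In unswitched memory cells the same kinds of genes were higher in infected donors. TBX21 rose by 4.34 ± 0.66, to 22.7 ± 8.40 from 1.07 ± 0.697 CPM (adjusted p = 0.0243). FCRL5 rose by 1.63 ± 0.25, to 721 ± 287 from 232 ± 53.3 CPM (adjusted p = 0.0243) and SOX5, a transcription factor of atypical memory cells, by 2.28 ± 0.37 (adjusted p = 0.0296). TNFSF4, the costimulatory ligand OX40L, fell by 3.16, from 26.5 ± 7.58 to 2.97 ± 1.99 CPM, and PTPRK, a receptor phosphatase, by 1.34, from 218 ± 31.5 to 86.3 ± 29.6. ITGAX was at 26.9 ± 14.9 against 3.53 ± 2.63 CPM (adjusted p = 0.106) and CXCR3 at 41.4 ± 19.5 against 9.91 ± 6.07 (adjusted p = 0.156). Of 42 interferon-stimulated genes 4 rose, and 32 adjusted over the list alone (camera adjusted p = 6.25e-53). Of 24 interferon-gamma genes 4 rose, and 14 adjusted over the list alone (camera adjusted p = 4.11e-29). Of 27 T-bet-high genes 4 rose, and 11 adjusted over the list alone (camera adjusted p = 2.19e-22). The 3 calls held with an estimated correlation. In total 14 genes were higher and 2 lower of 11205. DESeq2 called 97, edgeR without a low-count filter 66 and one model over all groups 48. The count was 10, 1 and 1 without uninfected unswitched replicates 1, 2 and 4, and 33, 7, 1 and 1 without HIV unswitched replicates 1 to 4.

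In memory cells FCRL4 rose by 3.99 ± 0.61, from 6.48 ± 4.59 in uninfected to 105 ± 73.0 CPM in infected donors (adjusted p = 0.0157). TBX21 rose by 3.05 ± 0.39, from 4.26 ± 2.09 to 36.2 ± 15.5 CPM (adjusted p = 0.00803), and FCRL5 by 1.66 ± 0.25, from 152 ± 9.90 to 494 ± 253 (adjusted p = 0.0157). IFIT3, an interferon-induced antiviral protein, was at 55.5 ± 46.0 against 4.98 ± 3.20 CPM, SOX5 at 45.7 ± 11.9 against 7.21 ± 4.60 and GPR34, a lysophospholipid receptor, at 43.0 ± 6.85 against 7.59 ± 2.74. SLC45A3 fell from 45.1 ± 9.88 to 15.8 ± 4.16 CPM, NEB from 42.6 ± 7.03 to 16.6 ± 4.22 and HGSNAT from 67.0 ± 7.76 to 31.2 ± 4.40. VASH2, named after its values were seen, was at 4.64 ± 3.68 in uninfected and 0.0916 ± 0.183 in infected donors (adjusted p = 0.0439). The fifth lower gene is of a kind not named here. ITGAX was at 68.4 ± 41.7 against 20.2 ± 26.7 CPM and did not pass (adjusted p = 0.485). The uninfected mean rested on replicate 4, at 67.6 CPM against 13.7 in the next library, and without it ITGAX rose by 3.02 (adjusted p = 0.0193). Of 28 T-bet-high genes 5 rose, and 13 adjusted over the list alone (camera adjusted p = 4.74e-21). Of 24 interferon-gamma genes 3 rose, and 14 adjusted over the list alone (camera adjusted p = 1.22e-25). Both held with an estimated correlation. Of 43 interferon-stimulated genes 5 rose, and 29 adjusted over the list alone (camera adjusted p = 1.11e-41, adjusted p = 0.0931 with an estimated correlation). Of 34 proliferation genes 2 rose, and 7 adjusted over the list alone (camera adjusted p = 1.07e-20, adjusted p = 0.102 with an estimated correlation). In total 28 genes were higher and 5 lower of 11589. DESeq2 called 188, edgeR 71 without a low-count filter, 50 in one model over all groups and 64 with the number of detected genes as a covariate. Without uninfected memory replicate 4, in which summed T cell markers reached 1510 CPM, the count was 80. It was 21, 4 and 16 without uninfected memory replicates 1, 2 and 3, and 5 without HIV memory replicate 3.

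**Figure D2:**
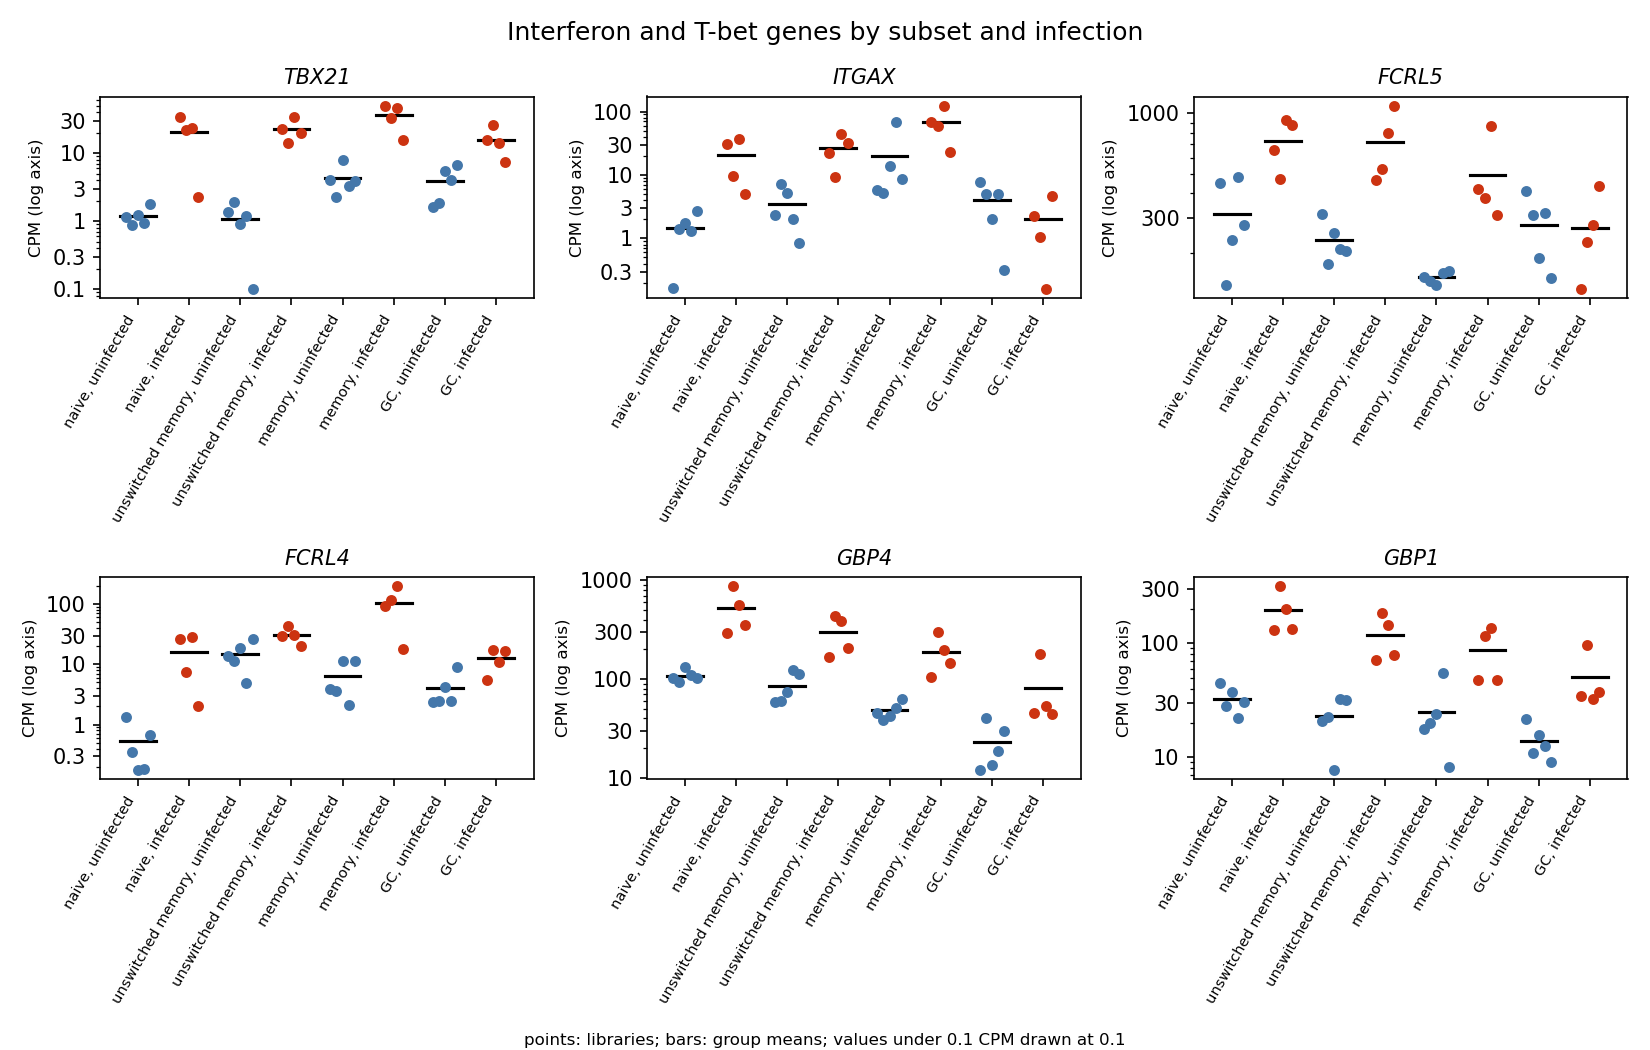
CPM on a log axis of TBX21, ITGAX, FCRL5, FCRL4, GBP4 and GBP1 in naive, unswitched memory, memory and GC cells, 1 point per library (5 uninfected, 4 infected) with a bar at each group mean. Mean TBX21 in naive cells is 20.4 CPM in infected and 1.20 in uninfected donors, and mean GBP1 is 195 and 32.6.

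In GC cells 6 genes passed with infection. LDHA, the lactate dehydrogenase of glycolysis, rose by 1.43 ± 0.22, from 170 ± 49.5 to 470 ± 103 CPM (adjusted p = 0.0428). RAG2, part of the V(D)J recombinase, fell by 6.96 ± 1.04, from 37.9 ± 27.1 to 0.287 ± 0.252 CPM (adjusted p = 0.0374), and PDE4D, a cyclic AMP phosphodiesterase, fell by 2.43 ± 0.35 (adjusted p = 0.0374). The 3 other called genes, SORT1, OR2T10 and KIAA1407, named after their values were seen, fell by 3.75, 4.03 and 2.18. TBX21 was at 15.6 ± 7.49 against 3.94 ± 2.23 CPM (adjusted p = 0.124) and BCL6 at 684 ± 96.9 against 649 ± 164 (adjusted p = 0.948). All 39 proliferation genes had a positive change with infection, of which 0 passed over all genes and 34 adjusted over the list alone (camera adjusted p = 8.29e-24, adjusted p = 0.149 with an estimated correlation). Of 21 glycolysis genes 1 rose, and 9 adjusted over the list alone (camera adjusted p = 1.22e-06, adjusted p = 0.156 with an estimated correlation). Of 21 interferon-gamma genes 0 passed over all genes and 8 were higher adjusted over the list alone (camera adjusted p = 3.05e-10, adjusted p = 0.103 with an estimated correlation). In the naive list 8 of 17 genes were lower adjusted over the list alone and 0 over all genes (camera adjusted p = 4.7e-06, adjusted p = 0.109 with an estimated correlation). This cannot be told apart from naive cells in the GC gate of uninfected donors. There, 100 genes at least 16-fold lower in GC than in naive cells of infected donors needed a median share of 9.51% naive cells. In total 1 gene was higher and 5 lower of 11566, while 1568 had an unadjusted p under 0.05. DESeq2 called 352, edgeR 228 in one model over all groups, 141 without a low-count filter and 29 with the number of detected genes as a covariate. The count was 0 without uninfected GC replicate 1 or 2 or HIV GC replicate 1, 2 or 3, 12 without HIV GC replicate 4, and 49, 33 and 35 without uninfected GC replicates 3, 4 and 5.

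Whether the infection effect differed between subsets was tested as a difference of differences. Between GC and naive cells it differed for 15 of 12228 genes, all with a smaller or more negative effect in GC cells. DHRS9, a retinol dehydrogenase, stood at 17.7 ± 12.4 CPM in infected and 0.137 in uninfected naive cells but at 71.4 ± 31.3 and 65.0 in GC cells, a difference of -6.61 ± 1.06 (adjusted p = 0.0103). DNAH8 gave -6.26 ± 0.89 (adjusted p = 0.00707) and TOX -4.34 ± 0.71 (adjusted p = 0.0108). Of 28 T-bet-high genes 2 differed, and 7 adjusted over the list alone (camera adjusted p = 1.28e-07), a call that held with an estimated correlation. TBX21 itself gave -2.10 ± 0.84 (adjusted p = 0.417) and ITGAX -4.79 ± 1.22 (adjusted p = 0.152). Of 42 interferon-stimulated genes 0 differed over all genes and 1 adjusted over the list alone (camera adjusted p = 2.33e-12, adjusted p = 0.113 with an estimated correlation). DESeq2 called 109 genes, edgeR 41 without a low-count filter, 42 in one model over all groups and 29 with the number of detected genes as a covariate, and 1 without infected donor replicate 3. With a replicate block the count was 16, of which 9 were among the 15, and GAB1, RNASE6, S1PR1, ZEB2, FAS and C18orf1 did not pass. Without infected donor replicates 1 and 4 the count was 8 and 9, and without uninfected donor replicates 1 and 2 it was 5 and 3. Between memory and naive cells edgeR called 0 of 12042 genes (431 with an unadjusted p under 0.05), DESeq2 called 1, edgeR with a replicate block 3 and edgeR without uninfected donor replicate 3 called 1. Between unswitched memory and naive cells edgeR called 0 of 11823 (312 with an unadjusted p under 0.05) and DESeq2 0. Both 431 and 312 are fewer than chance alone gives at that level. The test may have been strict, so 0 calls is weak evidence that the effects were alike. On simulated changes in genes with a mean of at least 20 CPM, the GC minus naive test found 65% of 4-fold and 11% of 2-fold effects. The other 2 differences were not simulated, nor was the pairing of a donor's libraries.

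Within infected donors, HIV-specific memory cells were compared with IgG+ memory cells to ask what sets antigen-specific cells apart. HIV-specific memory cells carried more transcripts of cell division. MKI67 rose by 2.22 ± 0.32, from 55.4 ± 25.1 to 270 ± 96.8 CPM (adjusted p = 0.00815), TOP2A, the topoisomerase of dividing cells, by 2.08 ± 0.34, from 26.6 ± 13.8 to 118 ± 39.0 (adjusted p = 0.0124), and the mitotic genes ZWINT, KIF23 and AURKA by 3.19, 2.81 and 2.63. Genes of T-bet-expressing memory cells were higher as well. TBX21 stood at 152 ± 73.0 against 41.7 ± 19.8 CPM (log2 change 1.79 ± 0.42, adjusted p = 0.0338), CXCR3 at 217 ± 79.9 against 65.2 ± 24.3 (adjusted p = 0.015), FAS at 433 ± 214 against 114 ± 49.3 (adjusted p = 0.0229) and ZEB2, a transcriptional repressor, at 945 ± 283 against 400 ± 138 (adjusted p = 0.0339). CR2 fell by 2.18 ± 0.30, from 632 ± 78.5 to 145 ± 60.4 CPM (adjusted p = 0.006), CXCR5 by 1.37 ± 0.25 (adjusted p = 0.0151), FCER2 by 2.85 ± 0.29 (adjusted p = 0.00157) and CXCR4 by 2.14 ± 0.39 (adjusted p = 0.0147). ITGAX was at 350 ± 290 against 107 ± 76.8 CPM (adjusted p = 0.105) and FCRL5 at 2190 ± 1030 against 742 ± 395 (adjusted p = 0.0511), and neither passed. Both were higher in the HIV-specific than in the IgG+ library of all 4 donors, and with a replicate block both passed, ITGAX at 1.53 (adjusted p = 0.000156) and FCRL5 at 1.47 (adjusted p = 0.00062). Of 39 proliferation genes 24 rose, and 37 adjusted over the list alone (camera adjusted p = 1.93e-27, adjusted p = 0.394 with an estimated correlation). Of 29 T-bet-high genes 8 rose, and 18 adjusted over the list alone (camera adjusted p = 4.26e-09, adjusted p = 0.394 with an estimated correlation). Of 19 genes low in T-bet-expressing cells 8 fell, and 9 adjusted over the list alone (camera adjusted p = 8.71e-08), which held with an estimated correlation. RGS13, a GC gene, was at 113 ± 186 against 11.1 ± 10.3 CPM and did not pass (adjusted p = 0.133). In total 337 genes were higher and 360 lower of 11418, 697 in all. The total was 2136 with a replicate block, 1545 with DESeq2 and 1429 without HIV-specific memory replicate 4. It was 354, 287 and 335 without HIV-specific memory replicates 1, 2 and 3, and 293, 148 and 172 without IgG+ memory replicates 1, 2 and 4.

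**Figure D3:**
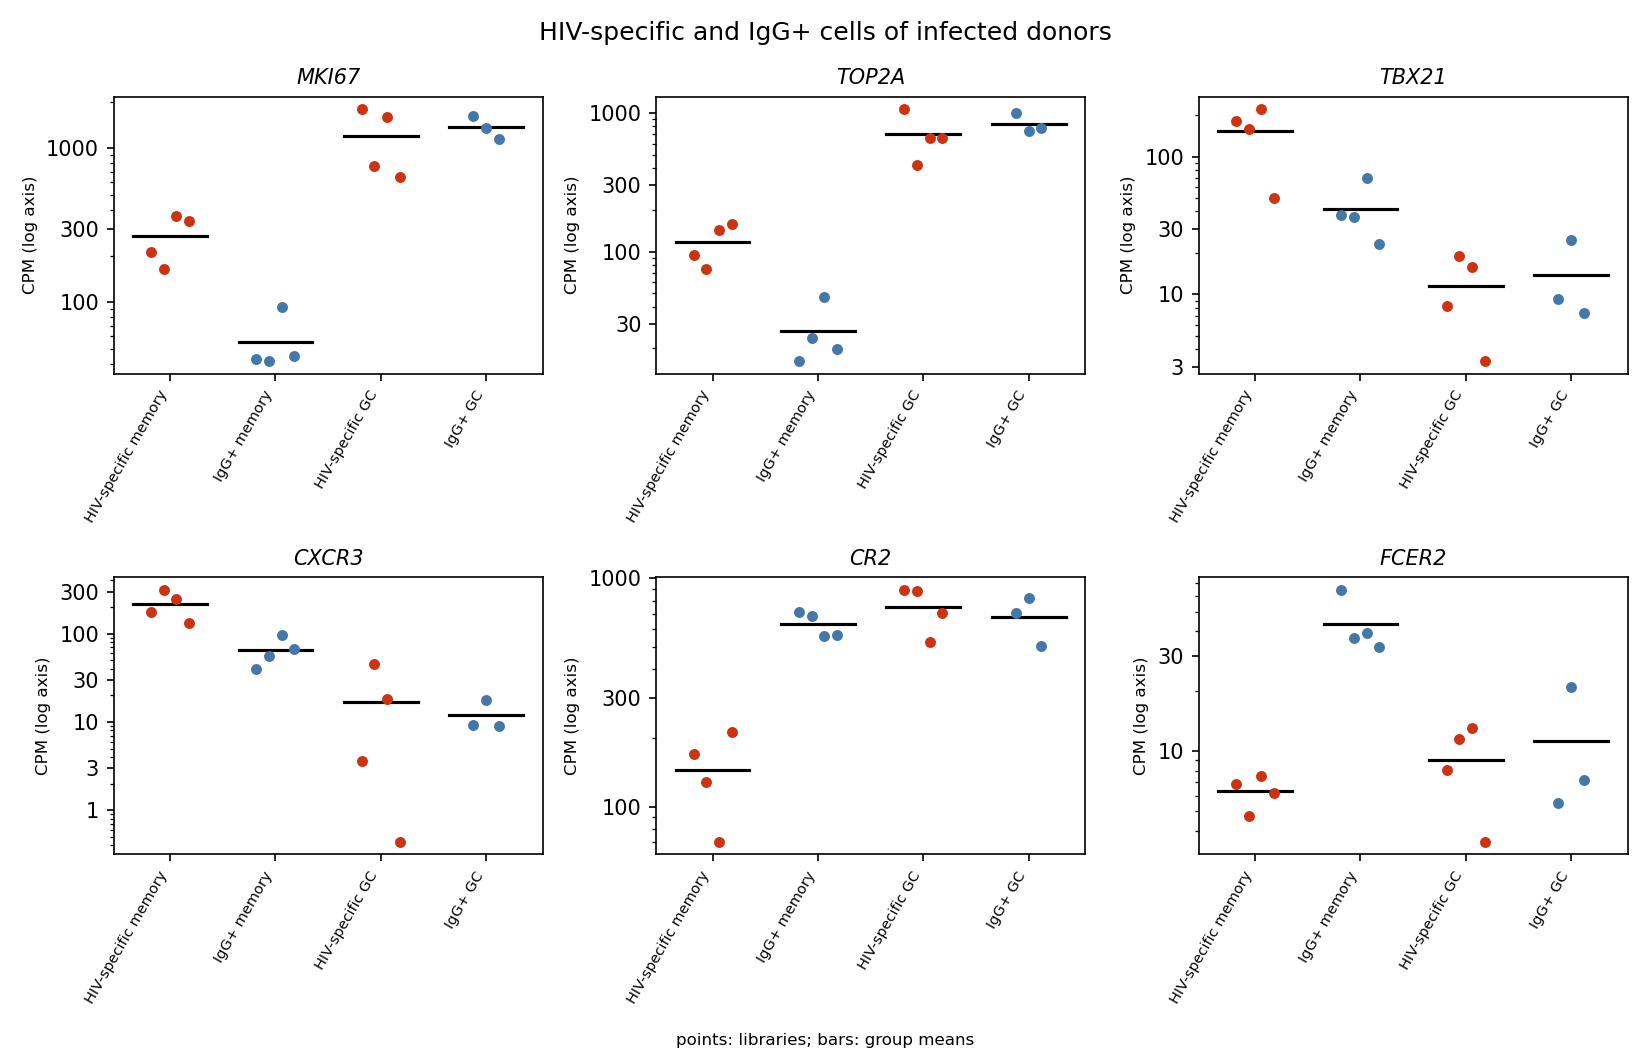
CPM on a log axis of MKI67, TOP2A, TBX21, CXCR3, CR2 and FCER2 in the 4 HIV-specific memory, 4 IgG+ memory, 4 HIV-specific GC and 3 IgG+ GC libraries, 1 point per library with a bar at each group mean. Mean MKI67 is 270 CPM in HIV-specific and 55.4 in IgG+ memory cells, and mean CR2 is 145 and 632.

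In GC cells the HIV-specific and IgG+ fractions were compared in the same way. edgeR called 0 of 11497 genes, with 322 at an unadjusted p under 0.05, and DESeq2 called 4. These 322 are fewer than chance alone gives at that level, so they are no sign of a difference. The test may have been strict here, so 0 calls is weak evidence of no difference. BCL6 stood at 572 ± 67.8 CPM in HIV-specific and 767 ± 51.7 in IgG+ GC cells, MKI67 at 1210 ± 580 and 1370 ± 232, TBX21 at 11.6 ± 7.12 and 13.8 ± 9.53, and CR2 at 751 ± 173 and 677 ± 157. ITGAX was at 24.9 ± 14.7 and 5.80 ± 3.51 CPM. Of 39 proliferation genes 0 passed, also adjusted over the list alone (camera adjusted p = 1.58e-05 with a lower direction, adjusted p = 0.805 with an estimated correlation). Summed T cell markers were at 236 ± 135 CPM in HIV-specific and 118 ± 18.7 in IgG+ GC cells, and summed monocyte and dendritic cell markers at 102 ± 127 and 22.1 ± 5.40. On simulated changes in genes with a mean of at least 20 CPM, the test found 95% of 4-fold and 34% of 2-fold effects at these group sizes. Changes in lower genes and the pairing of a donor's libraries were not simulated, so the shares may differ in these data.

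Memory and GC cells were then compared within each antigen class. In HIV-specific cells, FCRL4 was at 575 ± 289 CPM in memory and 9.67 ± 8.66 in GC cells, SIGLEC6 at 172 ± 68.2 and 2.16 ± 2.54, TBX21 at 152 ± 73.0 and 11.6 ± 7.12 (adjusted p = 0.000998), FCRL5 at 2190 ± 1030 and 299 ± 166 (adjusted p = 0.00158), CXCR3 at 217 ± 79.9 and 16.9 ± 20.6 (adjusted p = 0.0108), and ITGAX at 350 ± 290 and 24.9 ± 14.7 (adjusted p = 0.00166). CR2 was lower in memory cells, falling by 2.38 ± 0.32 (adjusted p = 0.000533), as were BCL6, which fell by 3.64 ± 0.44 (adjusted p = 0.000289), and MKI67, from 1210 ± 580 to 270 ± 96.8 CPM (adjusted p = 0.00166). Of 29 T-bet-high genes 20 were higher and 1 lower in memory cells, also adjusted over the list alone (camera adjusted p = 2.07e-15, adjusted p = 0.145 with an estimated correlation). Of 31 GC list genes 29 were lower, also adjusted over the list alone (camera adjusted p = 2.02e-34, adjusted p = 0.0949 with an estimated correlation). Of 39 proliferation genes 37 were lower, or 38 adjusted over the list alone (camera adjusted p = 1.5e-22, adjusted p = 0.241 with an estimated correlation). In total 1396 genes were higher and 1571 lower of 11398.

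In IgG+ cells, TBX21 was at 41.7 ± 19.8 CPM in memory and 13.8 ± 9.53 in GC cells (adjusted p = 0.0252), FCRL5 at 742 ± 395 and 294 ± 129 (adjusted p = 0.0316), ITGAX at 107 ± 76.8 and 5.80 ± 3.51 (adjusted p = 0.000782), CXCR3 at 65.2 ± 24.3 and 12.1 ± 5.03 (adjusted p = 0.000614), and NT5E, the ectoenzyme CD73, at 150 ± 59.9 and 1.84 ± 2.27. CR2, at 632 ± 78.5 and 677 ± 157 CPM, did not pass (adjusted p = 0.701). MME, the GC surface protein CD10, was at 3.16 ± 3.96 and 425 ± 141 CPM, BCL6 at 35.2 ± 5.83 and 767 ± 51.7, and MYBL1, a transcription factor of GC cells, at 4.12 ± 3.43 and 1230 ± 75.1. All 39 proliferation genes were lower in memory cells, also adjusted over the list alone (camera adjusted p = 1.28e-55), and of 31 GC list genes 30 were lower, or 31 adjusted over the list alone (camera adjusted p = 7.86e-39). Both held with an estimated correlation. Of 29 T-bet-high genes 17 were higher and 2 lower, or 17 and 3 adjusted over the list alone (camera adjusted p = 1.28e-05, adjusted p = 0.375 with an estimated correlation). In total 2248 genes were higher and 2434 lower of 11786. Whether the memory and GC difference itself differed between HIV-specific and IgG+ cells was not tested.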

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

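The tests of the explanations in this part were chosen after the results were seen, and the tests over other splits of the libraries were planned.

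T-bet and CD11c genes were higher in naive B cells of infected donors, where 5 genes of the T-bet-high list were called. Against library complexity, the number of detected genes was alike, at 12942 ± 759 in infected and 13026 ± 1040 in uninfected naive libraries. With this number as a covariate, 23 of the 23 called genes were called again. Since the groups hardly differ in it, the covariate could take away little, and this adds little support. Memory cells in the naive gate stay open and cannot be told apart from a change in naive cells: 40 other memory genes needed a median share of 2.25% of memory cells (5th to 95th percentile -12 to 43.8%, highest 79.4%), while FCRL4, FAS, ITGAX, SIGLEC6 and TBX21 needed 14.9, 25.9, 28.7, 44.4 and 55.0%. With HIV-specific memory cells as the source, the memory genes needed a median of 1.78% (5th to 95th percentile -37.7 to 188%) and the 5 genes 2.70 to 12.8%. A response of naive cells to interferon in infection stays a candidate explanation, not tested further, and GC cells in that gate were not tested. Summed plasmacytoid dendritic cell markers were at 50.3 ± 16.3 CPM in infected and 21.4 ± 10.2 in uninfected naive libraries. Summed T cell markers were at 65.7 ± 12.8 and 66 ± 24.8 CPM. Other cell types in the naive gate were not tested.

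Cell-cycle genes were higher in HIV-specific than in IgG+ memory cells. Against GC cells in the memory gate as the whole cause, 61 genes of GC cells outside the list needed a median share of 4.82% GC cells (quartiles 1.69 to 10.3%, 95th percentile 17.9%), while the 39 proliferation genes needed 20.6% (quartiles 17 to 24.7%). By library the GC genes needed 0, -0.165, 4.0 and 10.8% and the proliferation genes 4.73, 12.3, 22.5 and 38.6% for replicates 1 to 4; only in replicate 4 did the latter lie above the 95th percentile of the GC genes (33%), and its GC genes may mean that part of its signal came from GC cells. Without that replicate, 21 of the 39 proliferation genes were called higher, and 23 without replicate 1. Division of HIV-specific memory cells, or a group of dividing cells sorted with them, stays open as a biological explanation.

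The infection effect differed between GC and naive cells for 15 genes, by the test of the difference: DHRS9 (-6.61), DNAH8 (-6.26), LAIR1 (-4.42), TOX (-4.34), GAB1 (-4.08), KLF3 (-4.05), RNASE6 (-3.69), S1PR1 (-3.44), ABCA6 (-3.27) and PLXNC1 (-2.68, all log2), with ZEB2, FAS, KIAA1407, RNGTT and C18orf1; with a replicate block GAB1, RNASE6, S1PR1, ZEB2, FAS and C18orf1 did not pass (-3.46, -3.57, -3.13, -2.41, -2.65 and -2.85, adjusted p = 0.0726 to 0.0892), from -4.08, -3.69, -3.44, -2.60, -2.62 and -3.12. Naive cells in the GC gate of uninfected donors cannot be told apart from an infection effect for 7 of them, which needed a median of 15.2% of naive cells, against a median of 9.51% for 100 other naive genes (5th to 95th percentile -1.04 to 28.0%, highest 72.5%). S1PR1, RNASE6, LAIR1 and KLF3 needed 5.29, 7.42, 8.42 and 15.2%, and PLXNC1, ZEB2 and GAB1 needed 53.0, 55.4 and 80.2%. The 8 others, such as DNAH8 at 36.1 CPM in infected and 0.387 in uninfected naive cells, were not higher in naive than in GC cells of uninfected donors, so naive cells in that gate alone do not give their mean levels. An infection effect larger in naive than in GC cells for DHRS9, DNAH8, TOX and ABCA6 stays open, as for FAS, which did not pass with the block. Memory cells in the naive gate of infected donors stay open as well. DNAH8 was at 128 ± 109 CPM in infected memory and 36.1 ± 20.8 in infected naive cells.

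In 19 of 181 groups of values tested, 1 library lay far from the rest, where chance gives 9.05 for normally distributed values. CPM were tested without a log and some were near 0, so 19 cannot be read as an excess over chance. Summed T cell markers reached 1510 CPM in 1 uninfected memory library against 51.7 in the next. The total count was 12 M (mega) in 1 HIV-specific memory library against 6.47 M. RGS13 was at 391 CPM in 1 HIV-specific memory library against 47.9, and MKI67 at 92.9 in 1 IgG+ memory library against 44.5. MME was at 9.06 CPM in 1 IgG+ memory library against 1.58 and SIGLEC6 at 5.95 in 1 HIV-specific GC library against 1.15. In uninfected memory cells, IL4R was at 121 CPM in 1 library against 34.6, ITGAX at 67.6 against 13.7, HGSNAT at 80.6 against 65.8 and VASH2 at 11 against 4.24. VASH2 was at 0.366 CPM in 1 infected memory library against 0. In uninfected naive cells the highest library had CD27 at 15.9 against 1.77, CXCR3 at 3.54 against 0.932 and TOX at 4.25 against 0.997 CPM. In infected naive cells it had CD27 at 9.77 against 1.49, CCR7 at 107 against 70.1 and COL4A3 at 35.1 against 15.4 CPM. CCR7 was at 3.15 in 1 infected GC library against 0.653, and CD1C at 214 in the lowest uninfected unswitched library against 273.

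The planned splits tested whether other groupings of the libraries give as many called genes. Given are the real count, the splits with at least as many, and the highest other count. The real grouping is among the splits and is counted, so 1 of 100 means that no other drawn split gave as many. Where 35 splits are given, these were all the possible ones. The limit, fixed beforehand and not adjusted for the 17 comparisons, was a share of splits under 5%. Infection in memory cells met it (33, in 1 of 100 splits as many, highest other 11). The smallest share these splits could give was 1 of 100, so over 17 comparisons this argues against chance but does not exclude it. For naive (23, 4 of 100, 96), unswitched memory (16, 3 of 100, 90) and GC cells (6, 4 of 100, 42) the share was also under 5%. Their real counts lie within the range of the other splits, so the evidence against chance is weak. Why other splits called up to 96, 90 and 42 genes, several times the real counts, was not tested. Over all splits the share was under 5% in uninfected donors for memory (557, 1 of 100, 0), unswitched memory (208, 1 of 100, 129) and GC against naive cells (3281, 1 of 100, 0). The 129 came from a split that kept some donors' libraries together. The share over all splits was also under 5% in infected donors for memory (775, 1 of 35, 1), unswitched memory (276, 1 of 35, 1) and GC against naive cells (3949, 1 of 35, 0). The same held for HIV-specific against IgG+ memory (697, 1 of 35, 2), and for memory against GC cells in HIV-specific (2967, 1 of 35, 0) and IgG+ cells (4682, 1 of 35, 0). Most of these splits break the pairing of a donor's libraries. Splits that part as many pairs as the real one number 13 to 16 in uninfected and 8 in infected donors. These are too few for a share under 5%, so the splits do not exclude chance for the paired comparisons. The highest other count among them was 0. Where 0 genes were called, every split gives as many, so the splits decide nothing for HIV-specific against IgG+ GC cells (0, 35 of 35, 6) or for the differences of memory (0, 100 of 100, 23) and of unswitched memory from naive cells (0, 100 of 100, 0). For the difference between GC and naive cells the share was under 5% (15, 2 of 100, 20), with another split above the real count. The evidence against chance is weak here too.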

How the results depend on the processing

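The number of detected genes as a covariate was chosen after the results were seen; all other alternatives here were planned. The removal of immunoglobulin genes was not run, since the table names none, and the list of antibody constant genes had 0 members.

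With size factors by relative log expression every one of the 17 counts stayed within 1.5 times its value. No median of the 50 gene list results changed sign with it, and the median change of all genes shifted by at most 0.033. Of 292 gene results named and past the threshold, 196 stayed past it in all alternatives, and no called gene changed sign. Of 245 alternative counts, 167 stayed within 1.5 times and 78 moved further; the cause was not tested. Among named genes, leaving out 1 library or donor ended 332 and made 6 calls in 2677 values compared. Gene lists were retested with an estimated correlation, fry and, outside the infection comparisons, a replicate block. Of these 131 list results, 96 kept the outcome of the main test, 35 lost the call and 0 reversed. The list results above give the estimated correlation only, so calls lost with fry or the block are counted only here. With DESeq2 the counts were 115 for infection in naive cells, 97 in unswitched memory, 188 in memory and 352 in GC cells, 359 for unswitched memory against naive cells in uninfected and 520 in infected donors, 1211 for memory against naive cells in infected donors, 1545 for HIV-specific against IgG+ memory, 4 for HIV-specific against IgG+ GC, and 1 and 109 for the differences of memory and of GC from naive cells. Without a low-count filter, infection gave 96, 66, 71 and 141 in the same 4 subsets and the GC minus naive difference 41. In one model over all groups infection gave 99, 48, 50 and 228, memory and unswitched memory against naive cells of uninfected donors 925 and 615, and the GC minus naive difference 42. With a replicate block, unswitched memory against naive cells gave 415 in uninfected and 733 in infected donors, memory against naive cells of infected donors 1471, HIV-specific against IgG+ memory 2136 and the memory minus naive difference 3, and it moved no other count that far. With the covariate, infection gave 72 in naive, 64 in memory and 29 in GC cells, memory against naive cells of infected donors 57, GC against naive cells 2006 and the GC minus naive difference 29.

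Leaving out 1 library, the infection counts ran from 7 to 74 in naive, 1 to 33 in unswitched memory, 4 to 80 in memory and 0 to 49 in GC cells. Counts of subsets against naive cells ran in uninfected donors from 406 to 623 for memory, 134 to 237 for unswitched memory and 2707 to 3476 for GC cells, and in infected donors from 471 to 1139, 182 to 268 and 3385 to 3827. HIV-specific against IgG+ cells gave 148 to 1429 in memory and 0 to 0 in GC cells, and memory against GC cells 2093 to 3167 in HIV-specific and 3651 to 4512 in IgG+ cells. Leaving out 1 donor gave 0 to 1 for the memory, 0 to 0 for the unswitched memory and 1 to 22 for the GC difference from naive cells. The extremes came without HIV naive replicates 3 and 1, without uninfected memory replicates 2 and 4, without uninfected GC replicate 3, and without IgG+ memory replicate 2 and HIV-specific memory replicate 4. Genes far from the threshold changed sign with 1 library left out. BCL6 with infection in GC cells gave -0.02 without uninfected GC replicate 2, -0.06 without uninfected GC replicate 4 and -0.03 without HIV GC replicate 4, over a range of -0.06 to 0.17 with each library left out. In HIV-specific against IgG+ GC cells, MKI67 gave 0.01 and TBX21 0.07 without HIV-specific GC replicate 4, TBX21 gave 0.47 without IgG+ GC replicate 3 and CR2 gave -0.02 without IgG+ GC replicate 4; the ranges were -0.44 to 0.01 for MKI67, -0.61 to 0.47 for TBX21 and -0.02 to 0.30 for CR2. In IgG+ memory against IgG+ GC cells CR2 gave 0.05 without IgG+ GC replicate 3, in a range of -0.28 to 0.05. Groups held 3 to 5 libraries and totals were 4.69 to 12 M counts. How far each of these limited the size of change that could be found was not tested.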

Other observations

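The overlaps in this part were chosen after the results were seen.

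Infection calls were shared between naive, unswitched memory and memory cells. Of the 23 genes higher in naive cells and 13 in unswitched memory cells among genes tested in both, 10 were shared, where 0.0279 are expected if calls were independent. Naive and memory cells shared 6 (of 23 and 25, 0.0532 expected), and unswitched and memory cells 6 (of 14 and 27, 0.0342 expected). GC cells shared 0 calls with each of them, but with 1 higher call in GC cells at most 0.00239 were expected, so this decides nothing. Lower calls shared between any 2 subsets were 0, with at most 0.0011 expected. The same donors gave each subset, so these overlaps are not independent evidence.

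Of 30 ribosomal protein genes, 1 had a positive and the rest a negative change with infection in naive cells, with 0 past the test over all genes and 0 adjusted over the list alone (camera adjusted p = 8.62e-12, adjusted p = 0.243 with an estimated correlation). In GC against naive cells of infected donors, 16 of 29 oxidative phosphorylation genes rose, with the same count adjusted over the list alone (camera adjusted p = 0.00299, adjusted p = 0.439 with an estimated correlation). Summed plasma cell genes were at 2650 ± 520 CPM in uninfected and 1810 ± 220 in infected GC cells, and of 19 tested genes 5 were lower adjusted over the list alone and 0 over all genes (camera adjusted p = 4.7e-06, adjusted p = 0.232 with an estimated correlation). CD1C was at 267 ± 29.8 CPM in uninfected and 143 ± 33.1 in infected unswitched memory cells, which did not pass (adjusted p = 0.11).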
